A study of Mus musculus with 16 samples.

How the data were processed

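RNA was sequenced from whole subcutaneous white adipose tissue (scWAT) and from the left ventricle of the heart of 28-week-old mice of the C57BL/6J strain. The mice were labelled either wild-type or as carrying a deletion of HuR restricted to adipocytes. HuR is an RNA-binding protein encoded by Elavl1 that binds AU-rich elements in messenger RNAs. The 16 libraries came from 11 mice, 5 wild-type and 6 labelled knockout, and 5 mice gave both tissues, 4 of them wild-type and 1 labelled knockout. Adipose tissue was represented by 5 wild-type libraries (mice A5, A7, A8, A12 and A14) and 3 libraries labelled knockout (A24, A26 and A30). Heart was represented by 4 wild-type libraries (A5, A7, A8 and A14) and 4 libraries labelled knockout (A25, A29, A30 and A31). Groups and mouse numbers were taken from the sample labels alone. Each library of a group came from a different mouse, so replicate spread here is spread between animals.

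Per the labels' protocols, the frozen tissues were extracted with Trizol, and total RNA went into libraries made with an Illumina TruSeq kit. The authors deposited 1 table per library with a TPM value (transcript abundance scaled to a fixed total per library) for each gene symbol, per the file headers. The aligner, the quantifier, the annotation and the genome build are not given in the sources used here, and no coordinates are printed for that reason. TPM is scaled to the same total in every library, here 1e+06, so a large rise of some transcripts lowers all others. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval can be given. Values per gene do not show exons, so a transcript that lacks the deleted exons cannot be told from a complete one. Values of genes with near-identical copies, pseudogenes and predicted genes among them, depend on how reads were shared between the copies, and are uncertain for that reason.

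The tables held 33641 gene symbols. TPM values were analysed on the log2(TPM + 1) scale with a pseudocount of 1, which understates the change of low genes. In each tissue, genes with a mean of at least 1 TPM over the libraries of the fit were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean expression), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tests of genes, lists and Elavl1 were 2-sided, and the permutation test of neighbouring genes counted lists with at least as many pairs, on the upper side alone. Each tissue was fitted alone, because adipose tissue and heart have different genes and spreads. Whether the genotype difference itself differed between tissues was tested with an interaction term of tissue and genotype over all 16 libraries, on genes with a mean of at least 1 TPM in each tissue. Of the 41 gene lists fixed in advance (pathways and markers of cell types that the dissected tissue could hold), those with at least 5 tested members were tested with limma's camera at an inter-gene correlation of 0.01. That left 36 lists in scWAT and 32 in heart. Camera with an estimated correlation and limma's fry, a test of whether the genes of a list move one way on balance, were run as alternatives. Elavl1 and the mean log2(TPM + 1) of each list were also tested with an exact permutation test, whose smallest possible p is 0.0179 in scWAT and 0.0286 in heart. Because the median log2 fold change of all tested heart genes was 0.26, heart changes are given after subtracting that median, except where a value is named as not adjusted for it. Tests, and counts of genes or list members higher or lower, used the fold changes before that subtraction. Without A29 the median was 0.39, and that value was then subtracted.

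Genes were named by a rule. Elavl1 was always named. In each tissue, genes past the threshold with a mean of at least 5 TPM in the higher group and no overlap between the groups were named, up to 12 per direction by size of change, and where fewer passed, up to 6 per direction were filled by the smallest unadjusted p and are given as not passing. From each list that was primary in the tissue or past its threshold, up to 4 members with the smallest p could be named, and for the difference between tissues up to 5 genes per direction. Predicted genes and sex-linked genes were left out of the rule. Adipoq and Ccl21a in scWAT, Nppa, Nppb, Rab6b, Dkk3, Myl4, Bmp10, Myl7 and Sln in heart, Capn3, Pttg1, Fbxo44 and all predicted genes or pseudogenes were named after their values had been seen.

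The groups, tests, lists, naming rule and main alternatives were fixed before the data were examined. Alternatives were pseudocounts of 0.25 and 5, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, robust eBayes, array weights, a shared fit over all 16 libraries, a fold of at least 1.5 beside the adjusted p, leaving out each library in turn, and the mouse as a replicate block. The deposited tables of scWAT carried names of 2 styles, with the genotype (A5, A14 and A24) and without it (the other 5), and this style was used as a possible batch. Fits with skeletal muscle and B cell list means as covariates, and within the libraries of the plain style, were added after the data had been seen. The mouse numbers pair libraries of the same animal. Deviations from the group means correlated across genes between the tissues of the same wild-type mouse at 0.07 for A5, 0.03 for A7, 0.13 for A8 and 0.15 for A14, and scWAT of A7 correlated more with the heart of A5 (0.08).

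The pipeline was tested on simulated data made from the means and spreads of these libraries, with 200 genes changed by known folds in each tissue. In scWAT, over 13682 genes, 45% of 2-fold and 86% of 4-fold changes were recovered with the real spread, beside 9 false calls. In heart, over 11981 genes, 31% of 2-fold and 89% of 4-fold changes were recovered, beside 10 false calls. The simulated spread was independent between genes, and every simulated knockout library carried the same changes. These figures therefore do not hold where genes vary together or where a library departs from its group, as in the real libraries. Gene positions, used only to ask which genes neighbour each other, came from the RefSeq table of GRCm38.p6 and from GENCODE vM21. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.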

Results

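Transcript levels in subcutaneous white adipose tissue (scWAT) and in the left ventricle were compared between wild-type mice and mice in which HuR, the RNA-binding protein encoded by Elavl1, was to be removed from adipocytes alone. The design asks what loss of the protein in fat cells changes in fat, and what changes with it in the heart. There were 5 wild-type libraries and 3 libraries labelled knockout of scWAT, and 4 wild-type libraries and 4 labelled knockout of heart, all from mice aged 28 weeks. Values are TPM as deposited, and the depth of each library is unknown. Mitochondrially encoded transcripts took 8.70% ± 3.27 (SD, n = 5) of the TPM of wild-type scWAT and 11.4% ± 0.882 (n = 3) of scWAT labelled knockout. In heart they took 54.7% ± 3.99 (n = 4) in wild-type mice and 48.6% ± 5.24 (n = 4) in mice labelled knockout.

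Elavl1, the gene to be deleted, was not lower in the scWAT libraries labelled knockout. It stood at 33.4, 34.5, 27.6, 19.5 and 19.0 TPM in the wild-type libraries A5, A7, A8, A12 and A14, and at 42.9, 42.0 and 36.2 TPM in the libraries labelled knockout A24, A26 and A30. The means were 26.8 ± 7.39 TPM (SD, n = 5) and 40.4 ± 3.62 TPM (n = 3), a ratio of 1.51 in the direction opposite to the label. The log2 fold change was 0.61 (SE 0.22), and it did not pass the threshold (limma adjusted p = 0.256, exact permutation p = 0.0536, smallest possible 0.0179). With the means of the skeletal muscle and B cell lists as covariates the fold change was -0.19. Whole scWAT also holds cells in which the gene was not to be deleted, and a TPM per gene does not show whether the deleted exons were missing. The measured level therefore neither shows the deletion nor tests it, and every direction drawn below is between libraries labelled wild-type and libraries labelled knockout.

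In heart, where the gene was not to be deleted, Elavl1 stood at 10.4 ± 2.68 TPM (SD, n = 4) in wild-type libraries and at 10.9 ± 3.46 TPM (n = 4) in libraries labelled knockout. The log2 fold change, not adjusted for the shift of all genes, was 0.05 (SE 0.27), within the spread between mice (limma adjusted p = 0.926, exact permutation p = 0.857). Its sign turned to -0.25 with median-of-ratios scaling and to -0.23 with quantile normalization.

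The scWAT comparison asks which transcripts of fat differ with the label. Fabp3, the heart-type fatty acid binding protein, rose from 0.23 to 2.24 TPM in the 5 wild-type libraries to 44.9, 171 and 114 TPM in the libraries labelled knockout A24, A26 and A30 (log2 fold change 5.60, SE 0.47, limma adjusted p = 0.0046). The predicted gene Gm5905 rose as well, from at most 0.196 TPM to between 10.8 and 22.2 TPM (log2 fold change 3.95, SE 0.25, limma adjusted p = 0.00091). The predicted gene Gm45396 fell from between 3.50 and 6.21 TPM to between 0.129 and 0.304 TPM (log2 fold change -2.19, SE 0.23, limma adjusted p = 0.024). These 3 genes were the ones that passed the threshold among 13682 tested, while 2138 had an unadjusted p under 0.05, 1109 of them higher and 1029 lower in libraries labelled knockout. Groups did not overlap for 10.3% of the tested genes, where chance gives 3.57%.

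Genes with the next smallest p-values did not pass. Ucp1, the uncoupling protein of thermogenic adipocytes, was listed at 0.0401 to 1.16 TPM in wild-type libraries and at 8.85, 186 and 70.2 TPM in A24, A26 and A30 (log2 fold change 5.05, SE 0.78, limma adjusted p = 0.099), and it passed in 4 of 21 alternatives. The kinase gene Stk38 stood at 54.1 to 79.3 TPM in wild-type libraries and at 132 to 198 TPM in libraries labelled knockout (limma adjusted p = 0.069). The tubulin gene Tuba4a stood at 9.76 to 21.9 TPM and at 43.4 to 59.2 TPM (limma adjusted p = 0.069). Tmem265 stood at 2.42 to 4.08 TPM and at 8.14 to 8.96 TPM (limma adjusted p = 0.072). An immunoglobulin heavy chain segment gene had a log2 fold change of 2.81 and did not pass either. On the other side, Mfge8, a secreted glycoprotein that bridges dying cells to phagocytes, stood at 611 to 667 TPM in wild-type libraries and at 215, 202 and 355 TPM in A24, A26 and A30 (log2 fold change -1.35, SE 0.19, limma adjusted p = 0.069). The potassium channel gene Kcnj15 stood at 34.3 to 116 TPM and at 6.43 to 13.1 TPM, and Cacng7 at 20.1 to 28.8 TPM and at 8.88 to 12.6 TPM (limma adjusted p = 0.069 for both). Cela1, Mettl7b and Svip had log2 fold changes of -2.21, -1.50 and -1.21 (limma adjusted p = 0.169, 0.184 and 0.184).

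Of the gene lists, 6 passed the threshold in scWAT, all with higher values in libraries labelled knockout: skeletal muscle, sarcomere, cytosolic ribosomal proteins, thermogenic adipocyte program, T cell and B cell. None passed with an estimated correlation (adjusted p = 0.735 for each) or by fry (lowest adjusted p = 0.387). The thermogenic adipocyte program had a median log2 fold change of 0.62 over 18 tested members (camera adjusted p = 0.0013). No member passed over all genes, 4 were higher when adjusted over the list alone, and none was lower. Beside Ucp1, the fatty acid elongase Elovl3 stood at 0.0955 to 1.22 TPM in wild-type libraries and at 1.94, 36.1 and 9.23 TPM in A24, A26 and A30, and the lipid droplet protein gene Cidea at 13.5 to 52.9 TPM and at 52.9, 187 and 95.7 TPM. Cpt1b, the muscle-type carnitine palmitoyltransferase, stood at 3.99 to 11.0 TPM and at 11.9, 21.8 and 28.8 TPM. The exact permutation p of this list's mean was 0.0179, the smallest possible, and 0.321 after adjustment over the lists. No list could pass that adjustment alone, even at the smallest possible p.

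Markers of skeletal muscle and of lymphocytes were high in some scWAT libraries labelled knockout. The skeletal muscle list had a median log2 fold change of 4.81 over 13 members (camera adjusted p = 3.5e-09), and all 13 were higher when adjusted over the list alone. Myh4, a fast myosin heavy chain, stood at 270.2 TPM in A24, 13.9 TPM in A26 and 389.9 TPM in A30, against 37.2 TPM in the wild-type library A7 and at most 1.91 TPM in the other 4. Tnnt3, a fast troponin, reached 941 and 2104 TPM in A24 and A30, and 214 TPM in A7. The sarcomere list had a median log2 fold change of 2.08, with 15 of 16 members higher when adjusted over the list alone (camera adjusted p = 9.1e-08). Cacna1s, a calcium channel subunit of skeletal muscle, stood at 10.5, 3.91 and 18.1 TPM in A24, A26 and A30 and at no more than 1.01 TPM in wild-type libraries (limma adjusted p = 0.069). Lymphocyte markers were high in A26 alone. Cd79a, a subunit of the B cell receptor, stood at 177 TPM there and at no more than 7.33 TPM in every other scWAT library, and the lymph node chemokine Ccl21a at 1100.0 TPM and no more than 23.0 TPM. The T cell gene Cd4 stood at 38.8 TPM in A26 and at most at 1.83 TPM elsewhere. The T cell and B cell lists had median log2 fold changes of 1.69 and 1.52 (camera adjusted p = 0.0024 and 0.035) with 0 members past the threshold even adjusted over the list alone. The cytosolic ribosomal proteins were higher by a median of 0.44 (camera adjusted p = 0.00026), also with 0 members past either adjustment, and Rps6 stood at 1228 TPM in A26, 799 TPM in A24 and 655 TPM in A30 against 475 to 697 TPM in wild-type libraries. Over 23 alternatives, the B cell call ended in 9 and its test turned in 1, where the median was -0.22 without A26. The T cell call ended in 4 (median down to 0.19), the ribosomal call in 5 (down to 0.16), the thermogenic call in 3 and the sarcomere call in 2, while the skeletal muscle call ended in 2 and turned in 1.

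Genes of the mature adipocyte did not pass with all 8 libraries, as a list or singly. The list had a median log2 fold change of -0.14 over 20 members (camera adjusted p = 0.103). Adipoq, which encodes adiponectin, stood at 3956 to 6919.5 TPM in wild-type libraries and at 3299.8 to 5665 TPM in libraries labelled knockout. Without A24, and within the 5 libraries whose names carry no genotype, the list passed (2 of 23 alternatives, lowest adjusted p = 0.020). Its mean minus the wild-type mean was -0.50 in A26, -0.0017 in A24 and -0.061 in A30. Lep, which encodes leptin, stood at 764 to 2440.3 TPM and at 473 to 843 TPM (log2 fold change -1.35, SE 0.39, limma adjusted p = 0.22, passing in 1 of 21 alternatives), and Lpl, the lipoprotein lipase, at 4302 to 7948 TPM and at 2299 to 3542 TPM (log2 fold change -1.06, SE 0.29, limma adjusted p = 0.217). Scd1, a stearoyl-CoA desaturase of the lipogenesis list, had a log2 fold change of -1.04 (SE 0.33, limma adjusted p = 0.229), and the list itself a median of -0.23 (camera adjusted p = 0.201, passing in 2 of 23). The commonly cited targets of HuR had a median of 0.15 over 29 members (camera adjusted p = 0.249), and the direction of the test turned with array weights, with the covariates and without A26, while the list passed in 2 of 23 alternatives, without A24 and within the 5 libraries whose names carry no genotype (lowest adjusted p = 0.039). Of these, the cell cycle inhibitor gene Cdkn1b had the smallest p, at 9.77 to 16.1 TPM in wild-type libraries and 20.8 to 31.6 TPM in libraries labelled knockout (log2 fold change 0.90, SE 0.19, limma adjusted p = 0.216).

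**Figure D1:**
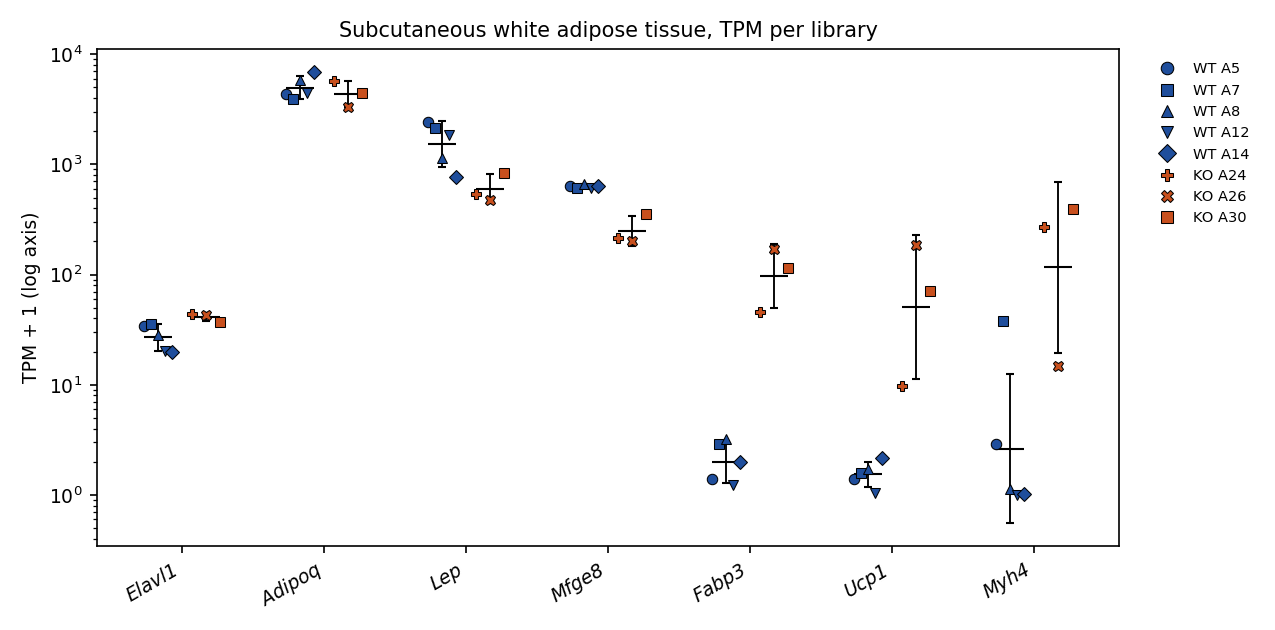
TPM + 1 of 7 genes in scWAT on a log axis, for each wild-type (WT, blue) and knockout-labelled (KO, orange) library, with bars at the mean and SD of the log2(TPM + 1) values. Elavl1 was not lower in libraries labelled KO, Fabp3 and Ucp1 were apart between the groups, and Myh4 was high in A24 and A30, at 270.2 and 389.9 TPM.

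The scWAT counts changed with single libraries, while Fabp3 and Gm5905 passed whichever library was left out. Gm45396 did not pass when any of the 5 wild-type libraries was left out. It also did not pass with a pseudocount of 5 or with the name style as a covariate. Without A26, the library with the lymphocyte markers, 124 genes were higher and 6 lower in libraries labelled knockout, without A30 the counts were 41 and 34, and without A24 they were 8 and 2. With the means of the skeletal muscle and B cell lists as covariates, none passed in either direction (660 at an unadjusted p under 0.05), with the name style as a covariate 2 were higher and none lower (2035 unadjusted), and within the 5 libraries of the plain name style, 3 wild-type and 2 labelled knockout, none passed (877 unadjusted). The other style held 2 wild-type libraries and 1 labelled knockout, too few for a value of its own.

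The heart comparison asks what changes in the left ventricle when the deletion is made in fat. Of 11981 tested genes, 6 rose in hearts labelled knockout and none fell (limma, 2508 higher and 439 lower at an unadjusted p under 0.05). These counts, and the p-values below, are of fold changes before subtracting the median of all genes. The mitochondrially encoded mt-Nd3, a subunit of respiratory complex I, rose from 1937 to 2619 TPM in wild-type hearts to 12775 to 15953 TPM in hearts labelled knockout, a log2 fold change of 2.36 after subtracting the median of all genes (SE 0.15, limma adjusted p = 2.5e-05). The potassium channel gene Kcnj14 rose from at most 0.815 TPM to 16.1 to 25.8 TPM, by 3.57 (SE 0.23, limma adjusted p = 2.8e-05). The predicted gene Gm5905 rose by 2.81 (SE 0.26), the predicted gene Gm13212 by 2.62 (SE 0.37), the small GTPase gene Rab6b by 1.36 (SE 0.21) and the pseudogene Znf41-ps by 1.82 (SE 0.29), with limma adjusted p = 0.00051, 0.024, 0.024 and 0.044. Groups did not overlap for 4.35% of the tested genes, where chance gives 2.86%.

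Many members of the fibrosis, cardiac hypertrophy and macrophage lists stood far apart between the wild-type hearts and 3 of the 4 hearts labelled knockout. On these lists the library A29, also labelled knockout, lay with the wild-type hearts. Over all tested genes, A29 correlated most with the wild-type heart A5 (Pearson r = 0.990), where pairs of wild-type hearts reached 0.977 to 0.988. Nppa, which encodes atrial natriuretic peptide, stood at 108 to 313 TPM in the 4 wild-type hearts, at 6980.4, 5021 and 5380.4 TPM in A25, A30 and A31, and at 52.7 TPM in A29. Nppb, which encodes brain natriuretic peptide, stood at 39.3 to 128 TPM in wild-type hearts, at 847, 594 and 691 TPM in A25, A30 and A31, and at 54.5 TPM in A29. With A29 in the fit neither passed (limma adjusted p = 0.152 and 0.149). Without A29, 4203 genes were higher and 502 lower in hearts labelled knockout among 12081 tested, and array weights, which give outlying libraries less weight, called 5160 higher and 2725 lower with all 8 libraries. Leaving out each library in turn was fixed in advance, but A29 was singled out because it lacked these differences. Results without it, here and below, are therefore no independent test of the label. They describe the other 3 hearts labelled knockout. Values of A29 are therefore given apart for many of the genes and lists below, lists as the mean log2(TPM + 1) of their members. These means include members too low to be tested and are not adjusted for the median of all genes.

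Of the gene lists, 20 passed the threshold in heart, 10 in each direction. None passed with an estimated correlation (adjusted p = 0.628 to 0.687) or by fry (lowest adjusted p = 0.279). Without A29, 22 lists passed by camera, 14 by fry and none with an estimated correlation (lowest adjusted p = 0.454). With median-of-ratios scaling, with quantile normalization and without mitochondrially encoded genes, 17 passed by camera in each case. The exact permutation test of list means passed for none (lowest adjusted p = 0.332). Its smallest possible p, 0.0286, cannot pass after adjustment over the lists unless many lists reach it together, so this outcome says little.

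The fibrosis and extracellular matrix list was higher by a median log2 fold change of 1.84 over 30 members (camera adjusted p = 1.2e-08), and 24 were higher when adjusted over the list alone, with none past the threshold over all genes. Without A29, 29 of the 30 were higher past the threshold over all genes. Periostin (Postn), a matrix protein of activated fibroblasts, stood at 8.43 to 20.6 TPM in wild-type hearts, at 934, 1016 and 1322 TPM in A25, A30 and A31, and at 13.1 TPM in A29. Comp, the cartilage oligomeric matrix protein, stood at no more than 0.832 TPM in wild-type hearts, at 106, 87.2 and 75.7 TPM in A25, A30 and A31, and at 0.518 TPM in A29. The fibroblast and adipose progenitor list was higher by 0.94 over 14 members, 9 of them higher when adjusted over the list alone (camera adjusted p = 0.0013), and decorin (Dcn) stood at 152 to 205 TPM in wild-type hearts, at 723, 662 and 825 TPM in A25, A30 and A31, and at 180.0 TPM in A29.

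The cardiac hypertrophy and fetal program was higher by a median of 1.42 over 12 members, 8 of them higher when adjusted over the list alone (camera adjusted p = 0.0011). Acta1, the skeletal alpha-actin expressed in the fetal heart, stood at 48.2 to 183 TPM in wild-type hearts, at 1563, 2270.0 and 1201 TPM in A25, A30 and A31, and at 191 TPM in A29. Gdf15, a secreted stress factor, stood at no more than 1.19 TPM in wild-type hearts, at 16.1, 27.0 and 17.6 TPM in A25, A30 and A31, and at 0.343 TPM in A29. The mean log2(TPM + 1) of 5 markers of atrial heart muscle, too few of them expressed for a list test, was 0.38 to 0.55 in wild-type hearts, 1.43 to 1.73 in A25, A30 and A31, and 0.36 in A29. Most of this difference came from Dkk3, at 0.343 to 0.870 TPM in wild-type hearts, 21.6, 13.8 and 19.2 TPM in A25, A30 and A31, and 0.426 TPM in A29. Myl4 was higher in the same hearts, at 0.934 to 1.85 TPM, 4.86, 3.87 and 4.17 TPM, and 1.25 TPM. Bmp10 was too, at no more than 0.0432 TPM, 0.417, 0.366 and 0.468 TPM, and 0.0262 TPM. The atrial light chain gene Myl7 reached 1.33 TPM and sarcolipin (Sln) 0.138 TPM at most. The sarcomere list was lower by a median of -0.54 over 20 members, with no member past either adjustment (camera adjusted p = 8.4e-05). Without A29, the list had 4 members higher and 4 lower past the threshold over all genes. Its members moved apart: Myh6, the adult alpha-myosin heavy chain, stood at 2170.4 to 4769 TPM in wild-type hearts and at 1115, 2933 and 1012 TPM in A25, A30 and A31, while desmin (Des) stood at 340.1 to 541 TPM and at 1235, 1295 and 982 TPM. A29 had 2399 TPM of Myh6 and 428 TPM of Des.

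The immune and stress lists that passed were higher too. The macrophage list was higher by a median of 1.53 over 19 members, 17 of them higher when adjusted over the list alone (camera adjusted p = 2.5e-06). Lyz2, which encodes lysozyme, stood at 72.3 to 115 TPM in wild-type hearts, at 664, 680 and 886 TPM in A25, A30 and A31, and at 74.5 TPM in A29. Inflammatory cytokines and chemokines were higher by 1.04, with 12 of 21 members higher when adjusted over the list alone, complement and acute phase genes by 0.78, with 3 of 12, the unfolded protein and integrated stress response by 0.96, with 15 of 20, heat shock genes by 0.47, with 4 of 13, and cytosolic ribosomal proteins by 0.67, with 21 of 22 (camera adjusted p = 0.00056, 0.0071, 0.00031, 0.030 and 2.9e-09). The cell cycle list was higher by 0.73 over 16 members, with 0 past either adjustment (camera adjusted p = 0.00074). Without A29, 15 of its 16 members were higher past the threshold over all genes. The heat shock call ended in 7 of 20 alternatives, median-of-ratios scaling and removal of mitochondrially encoded genes among them. A29 had list means of 5.77 for heat shock (5.60 to 6.40 in wild-type hearts, 6.65 to 7.52 in A25, A30 and A31), 7.13 for ribosomal proteins (6.90 to 7.29 and 8.21 to 8.44) and 0.87 for cell cycle (0.86 to 1.36 and 2.42 to 2.51). The chemokine gene Ccl8 stood at 0.697 to 2.46 TPM in wild-type hearts, at 52.3, 69.9 and 116 TPM in A25, A30 and A31, and at 0.832 TPM in A29. Serpina3n, an acute phase protease inhibitor, stood at 2.62 to 7.82 TPM, at 192, 215 and 229 TPM, and at 2.77 TPM in A29, and Mthfd2, a mitochondrial folate enzyme induced by the integrated stress response, at 1.01 to 1.61 TPM, at 17.7, 20.3 and 18.2 TPM, and at 0.839 TPM in A29.

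Fatty acid oxidation was lower by a median of -0.70 over 28 members, with 0 past either adjustment (camera adjusted p = 3.5e-10), and nuclear-encoded oxidative phosphorylation by -0.36 over 27 members, also with 0 (camera adjusted p = 7.9e-06). Without A29 the medians were -1.05 and -0.58. Past the threshold over all genes, 17 fatty acid oxidation members were then lower and 1 higher, and 6 oxidative phosphorylation members lower and 0 higher. Hadh, an enzyme of mitochondrial beta-oxidation, stood at 226 to 339 TPM in wild-type hearts, at 107, 116 and 104 TPM in A25, A30 and A31, and at 342 TPM in A29. Calcium handling and ion channels were lower by -0.80 over 21 members, 5 of them lower when adjusted over the list alone (camera adjusted p = 5.1e-09). Atp2a2, the calcium pump of the sarcoplasmic reticulum, stood at 2523 to 4045 TPM in wild-type hearts, at 1382, 2174 and 1242 TPM in A25, A30 and A31, and at 2750.2 TPM in A29, and the potassium channel gene Kcnj3 at 18.6 to 27.1 TPM, at 2.76, 4.45 and 2.48 TPM, and at 17.0 TPM in A29. The circadian clock list was lower by -0.87, with 1 of 16 members lower when adjusted over the list alone (camera adjusted p = 6.0e-05). Its mean in A29 was 2.87, within the range of the wild-type hearts (2.58 to 3.52) and within that of A25, A30 and A31 (2.80 to 3.35). The mean of nuclear-encoded oxidative phosphorylation in A29 was 9.27, above the wild-type hearts (8.84 to 9.23) and A25, A30 and A31 (8.75 to 8.86).

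Mitochondrially encoded transcripts were lower as a list by -0.58 over 13 members (camera adjusted p = 5.8e-05), with none lower past either adjustment and mt-Nd3 higher past both, so the list and this member went opposite ways. The direction of the list's test turned with quantile normalization, where its median log2 fold change was -0.05. Of the lists named for fat or its functions, 4 were lower, while fibroblast and adipose progenitor was higher and secreted adipose factors, at 0.72, did not pass (camera adjusted p = 0.164). The lower ones were lipogenesis by -0.41, the thermogenic adipocyte program by -0.49, lipolysis and lipid droplet by -0.49 and mature adipocyte by -0.55 (camera adjusted p = 0.0013, 0.0061, 0.015 and 0.015). Beside the estimated correlation and fry, the last 3 calls ended with median-of-ratios scaling and with quantile normalization, and over all 20 alternatives the thermogenic call ended in 6, lipolysis in 5 and mature adipocyte in 6. Their means in A29, at 3.01, 2.85, 3.60 and 1.83, lay within the ranges of the wild-type hearts. For lipogenesis and lipolysis they also lay within the ranges of A25, A30 and A31 (2.90 to 3.59 and 3.43 to 3.80). For the thermogenic and mature adipocyte lists they lay below those hearts (2.855 to 3.127 against 2.848 in A29, and 1.95 to 2.20). These means took in all 20 listed members of each list, against 12 and 10 tested, without subtracting the median of all genes. On them the wild-type hearts (2.65 to 3.03 and 1.82 to 2.70) overlapped A25, A30 and A31, so they do not set the groups apart. A29 is therefore not placed with either group by these lists. The members of these lists in heart included genes that heart muscle uses itself, such as Lpl, at 1037 to 1418 TPM in wild-type hearts, 602, 813 and 475 TPM in A25, A30 and A31, and 1048 TPM in A29. Adjusted over the list alone, 4 thermogenic members were lower and 2 higher, 2 mature adipocyte members were lower, and 0 members of the other lists passed.

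Among single genes that did not pass, the naming rule picked some that were apart between all 4 wild-type hearts and all 4 hearts labelled knockout, A29 included. Being apart was thus a condition of the choice. Over all 11981 tested genes, 445 were apart with higher and 76 with lower values in hearts labelled knockout, where chance gives 2.86% over both directions. Klhl38, a muscle gene of the kelch-like family, stood at 15.8 to 18.5 TPM in wild-type hearts and at 5.28 to 8.60 TPM in hearts labelled knockout, 8.60 TPM being A29 (limma adjusted p = 0.142, as for each gene in this paragraph). Adra1a, the alpha-1A adrenergic receptor, stood at 4.17 to 11.0 TPM and at 0.591 to 3.61 TPM, Fbxo32, a muscle ubiquitin ligase, at 18.8 to 32.8 TPM and at 7.64 to 15.2 TPM, and the transcription factor Klf15 at 18.7 to 31.2 TPM and at 5.54 to 13.5 TPM. Ybx2 and Rbfox1, genes of nucleic acid binding proteins, had log2 fold changes of -1.85 and -1.96 after subtracting the median of all genes. Higher in the same way were Hddc3, at 18.9 to 30.1 TPM and at 41.3 to 50.7 TPM, and the zinc finger genes Zfp982, Zfp984 and Zfp969, with changes of 2.03, 1.68 and 1.22.

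**Figure D2:**
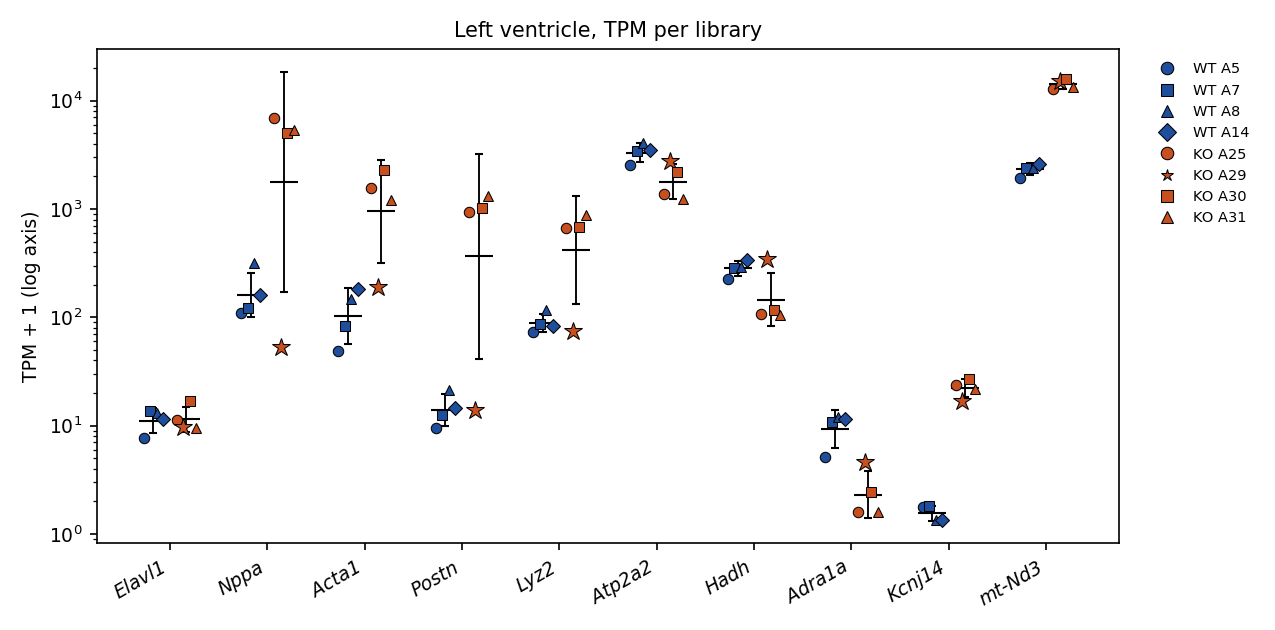
TPM + 1 of 10 genes in the left ventricle on a log axis, for each wild-type (WT, blue) and knockout-labelled (KO, orange) library, with bars at the mean and SD of the log2(TPM + 1) values. The library A29 (star) lies with the wild-type hearts for Nppa at 52.7 TPM, Acta1, Postn, Lyz2 and Hadh, and with the other hearts labelled KO for Kcnj14 at 16.1 TPM and mt-Nd3 at 15061 TPM.

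**Figure D3:**
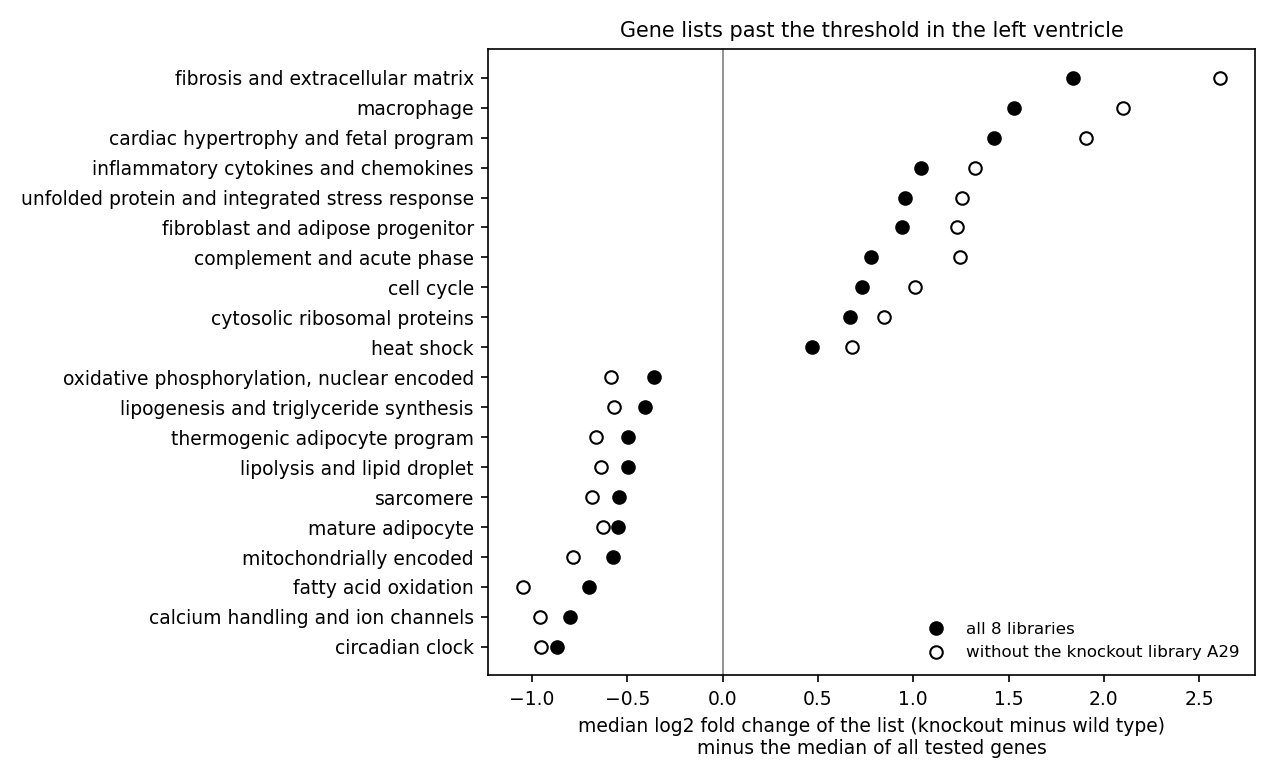
Median log2 fold change of the 20 gene lists past the threshold in the left ventricle, minus the median of all tested genes, with all 8 libraries (filled) and without A29 (open). The fibrosis list lies at 1.84 with A29 and at 2.61 without it, and fatty acid oxidation at -0.70 and -1.05.

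The median log2 fold change of all tested heart genes was 0.26 as deposited, -0.02 with median-of-ratios scaling, -0.02 with quantile normalization and 0.11 without mitochondrially encoded genes. The count of genes higher in hearts labelled knockout was 3 to 7 when a library other than A29 was left out, and the count of genes lower was then 0 or 1 (1 without A5 and 1 without A30). Gm13212, Rab6b and Znf41-ps did not pass when any of A5, A7, A8, A25, A30 or A31 was left out, Rab6b also not without A14, and mt-Nd3 did not pass in the shared fit over all 16 libraries.

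Whether a genotype difference itself differed between the tissues was tested over 11536 genes, and 7 passed. Kcnj14 was higher in hearts labelled knockout but not in scWAT (difference of log2 fold changes, heart minus scWAT, 4.82, SE 0.75, limma adjusted p = 0.016). The other 6 had the larger value in scWAT: Fabp3 (-5.26, SE 0.50, limma adjusted p = 0.0001), Cacna1s (-3.79), the muscle protease gene Capn3 (-2.35), Fam134b (-2.45), Ybx2 (-2.43) and the muscle ubiquitin ligase gene Asb2 (-3.47), with adjusted p-values between 0.0027 and 0.036. The call of Asb2 ended in 14 of 25 alternatives and that of Ybx2 in 12 of 26, with adjusted p up to 0.114 for both, 1 of 26 ended that of Kcnj14, and those of Fabp3, Cacna1s and Fam134b held in each alternative run on them. Cacna1s, Capn3 and Asb2 are genes of skeletal muscle, whose markers were high in the scWAT libraries A24 and A30. Before adjustment 2360 genes had a p under 0.05. With the mouse as a replicate block, 7 genes passed, the same 7 (consensus correlation within mouse -0.04). Without A29 there were 2863, without the scWAT library A26 94, without A30 of scWAT 23, and without A5 of heart 12. Median-of-ratios scaling gave 272 and quantile normalization 216.

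Only Gm5905 passed the threshold in both tissues, in the same direction, where independent lists would share 0.00087 genes. Across the 11536 genes tested in both tissues, the log2 fold changes of scWAT and heart had a Pearson correlation of 0.05 and the same sign for 51.8% of genes, and genes are not independent replicates. Groups did not overlap in both tissues in the same direction for 28 genes, against 25.1 expected from independent lists, and in opposite directions for 22, against 24.6.

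**Figure D4:**
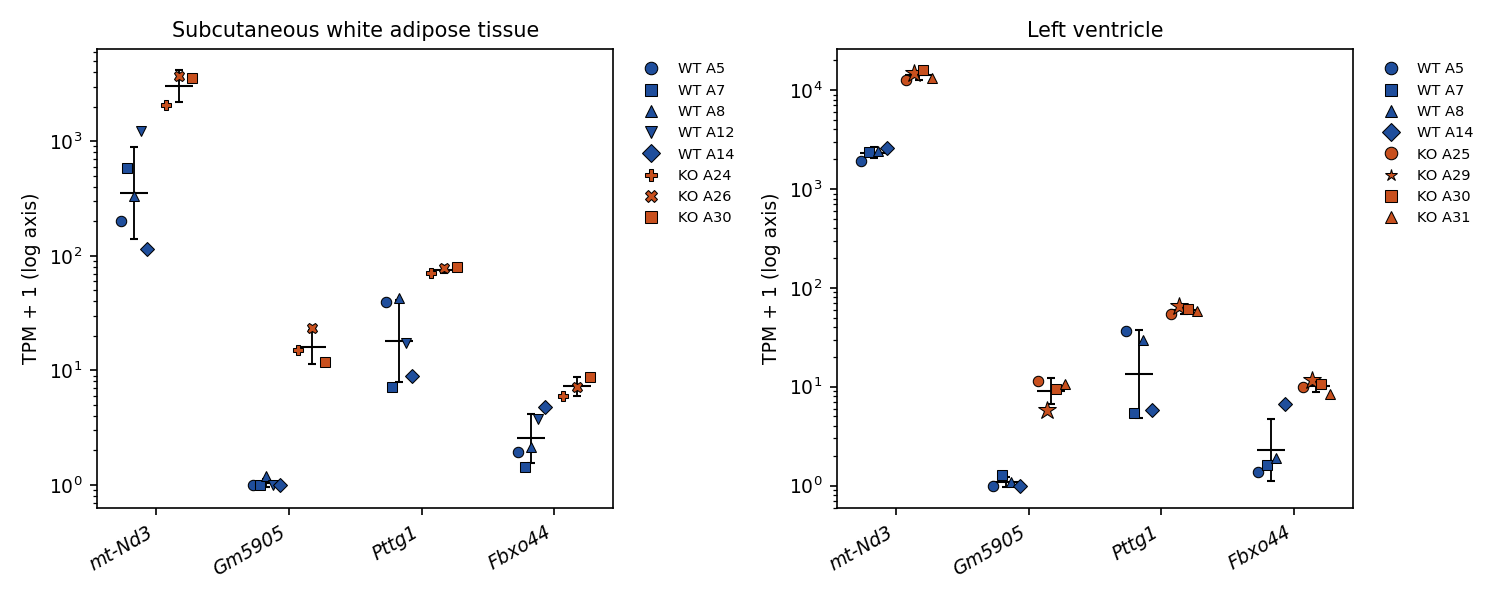
TPM + 1 of mt-Nd3, Gm5905, Pttg1 and Fbxo44 on a log axis in scWAT and heart, for each wild-type (WT, blue) and knockout-labelled (KO, orange) library, with bars at the mean and SD of the log2(TPM + 1) values. In both tissues every library labelled KO lies above every WT library, and Gm5905 is listed at no more than 0.284 TPM in WT libraries.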

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

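Both tests of a wrong label for A29 were chosen only after the result had been seen, the second after the outcome of the first. The fits with skeletal muscle and B cell covariates and the splits of mice for the difference between tissues were also added after the data had been seen.

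Of 106 sets of libraries examined for a library far from the others of its group, 20 held one, where chance gives about 5.3. Among hearts labelled knockout, A29 was lowest on the mean log2(TPM + 1) of cardiac hypertrophy and fetal program at 4.59 (others 7.0 to 7.48), macrophage at 2.47 (4.84 to 5.17), unfolded protein and integrated stress response at 3.32 (4.92 to 5.18), cell cycle at 0.87 (2.42 to 2.51), fibroblast and adipose progenitor at 4.22 (5.87 to 6.08) and complement and acute phase at 2.17 (4.15 to 4.40). A30 was highest there on lipogenesis at 3.59 (2.90 to 3.01) and on the thermogenic adipocyte program at 3.13 (2.85 to 2.88).

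Among wild-type hearts, A5 had the highest mitochondrially encoded share of TPM, 60.6% (others 51.9% to 53.2%), and the lowest list means for fibrosis at 1.82 (2.47 to 2.60), calcium handling at 5.02 (5.63 to 5.69) and circadian clock at 2.58 (3.42 to 3.52). Adra1a was lowest in A5 as well, at 2.37 on the log2(TPM + 1) scale (3.42 to 3.58). In A14, Zfp982 was highest at 2.50 (0.38 to 0.53), as was Zfp984 at 1.49 (0.55 to 0.68).

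Among wild-type scWAT libraries, A12 had the highest mitochondrially encoded share, 14.4% (others 6.14% to 8.41%), the lowest mean of the interferon response list at 3.62 (3.94 to 4.07) and the highest mean of the B cell list at 2.42 (1.29 to 1.55). An immunoglobulin heavy chain segment gene was highest in A8 at 0.78 (0 to 0.22), and Cacna1s in A7 at 1.01 (0.15 to 0.30).

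The genotype difference differed between the tissues, by the interaction test, for 7 genes. The difference of log2 fold changes, heart minus scWAT, was 4.82 for Kcnj14, -5.26 for Fabp3, -3.79 for Cacna1s, -3.47 for Asb2, -2.45 for Fam134b, -2.43 for Ybx2 and -2.35 for Capn3. Among 100 permutations of the labels within each tissue, the real one included, 5 gave at least 7 genes and the highest other gave 1050, a share at the bound of 5%. These permutations let a mouse carry different labels in its scWAT and its heart. Among 100 splits in which each mouse kept 1 label in both tissues, 8 gave at least 7 genes and the highest other gave 1984, so chance is not excluded for this count.

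The heart library A29, labelled knockout, lay with the wild-type hearts on lists such as fibrosis, hypertrophy and macrophage. Positions were taken on a scale from the wild-type mean (0) to the other hearts labelled knockout (1). A29 stood there at 0.47 on the sarcomere list and at 0.41 on the calcium handling list. On both lists the groups overlapped and A29 lay within both ranges, so these lists do not place it. A high share of mitochondrial RNA in the library is argued against as an effect of TPM scaling alone: on the same scale, A29 stood at -0.14 on the hypertrophy list, and at -0.13 (spread 0.14) with mitochondrially encoded genes left out. Leaving them out moves all other genes of a library by a common factor. With shares of 55.7% in A29 and 43.4% to 48.9% in A25, A30 and A31, that factor was too small to close the gap. The test therefore says nothing on RNA quality or other differences between libraries. A wild-type mouse with a knockout label stays open. Of 22 genes apart by more than 0.3 log2 in both tissues without A29, A29 was nearer the other hearts labelled knockout at 5. The same held at 18 of all 289 genes apart by any gap. Most of these genes were chosen on the heart response itself, so both counts largely restate that A29 lacked it and cannot decide the label. In the second test A29 sat at the level of those hearts at 5, 5, 4 and 6 genes as A5, A7, A8 and A14 were left out in turn, against 2, 0, 2 and 1 for the wild-type heart left out. The bound against a wrong label, at least 5 genes and more than any wild-type heart by over 2 times, was met in all settings but the one with 4, and taken on the lowest count the test decides neither way. In A29, mt-Nd3 (15061 TPM), Kcnj14 (16.1 TPM), Pttg1 (64.4 TPM) and Fbxo44 (10.6 TPM) were at the knockout-labelled level. Gm5905 (4.87 TPM) lay between the groups, below A25, A30 and A31 (10.3, 8.43 and 9.72 TPM). At each of these genes A29 lay above every wild-type heart, though the genes were picked with A29 among the hearts labelled knockout. A difference in the course of disease between mice, or in the deletion itself, also stays open and was not tested.

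In scWAT, Fabp3 and Ucp1 were apart between the groups in libraries that also differed in skeletal muscle and lymphocyte markers. With the means of the muscle and B cell lists as covariates, the log2 fold change of Fabp3 went from 5.60 (SE 0.47) to 3.93 (SE 1.08), and that of Ucp1 from 5.05 (SE 0.78) to 3.75 (SE 1.67). Neither passed (limma adjusted p = 0.861 for both), and Ucp1 was not past 0.05 before adjustment either. The bounds set in advance were 2 standard errors and a fixed share of the value without the covariates. Fabp3 stayed above both by more than its spread, which argues against tissue tracked by these 2 lists as its whole source. Ucp1 stayed above them by less than its spread, so carried-over tissue of both kinds stays open for Ucp1. The lists hold markers of largely fast skeletal muscle and of B cells, so other muscle and thermogenic fat were not adjusted for. The call of Fabp3 ended because the fold shrank and its error grew, as the covariates and the label vary together over 8 libraries. With the B cell covariate alone both passed, Fabp3 at 5.31 (SE 0.49, limma adjusted p = 0.0028) and Ucp1 at 4.29 (SE 0.68, limma adjusted p = 0.025). With the muscle covariate alone neither passed, Fabp3 at 5.63 (SE 0.78) and Ucp1 at 6.24 (SE 1.19, limma adjusted p = 0.128 for both). A part from muscle, and thermogenic fat taken with the pad or arising in it, could each contribute and stay open.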

How the results depend on the processing

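Adjustment for skeletal muscle and B cell lists and the fit within the plain name style were added after the data had been seen. Robust eBayes and a pseudocount of 0.25 left every count of genes and lists within 1.5 times its value. A fold of at least 1.5, applied only to the counts of genes in each tissue, left those unchanged. A sex covariate was not run, since all 16 libraries express Y-linked genes and Xist is not among the genes of the files. TPM keeps no depth, so what depth limits is unknown. Where no reason is given, the cause was not tested.

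Array weights called 66 higher and 14 lower genes in scWAT, 5160 and 2725 in heart, 5263 for the difference between tissues and 17 shared between tissues. The shared fit over 16 libraries called 76 and 59 genes in scWAT and 3 higher in heart. Without a filter, 5 genes were higher in scWAT, 12 scWAT lists passed, 2 genes were lower in heart and 17 differed between tissues. With at least 5 TPM, where fewer genes are tested, scWAT gave 1 higher and 0 lower, heart 2 higher, the difference 3 and the overlap 0. A pseudocount of 5 gave 0 lower in scWAT and 11 for the difference. Median-of-ratios scaling gave 4 higher in scWAT and 272 for the difference, quantile normalization 4, 14 scWAT lists and 216, and removal of mitochondrially encoded genes 17 for the difference. The name style as a covariate gave 0 lower in scWAT. The plain style alone, with fewer libraries, gave 0 higher, 0 lower and 16 lists, and the muscle and B cell covariates 0 and 0. With an estimated correlation, and by fry, 0 lists passed in scWAT and 0 in heart.

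Leaving out each library in turn gave 2 to 124 higher (124 without A26) and 0 to 34 lower (34 without A30) in scWAT, 6 to 14 scWAT lists, 3 to 4203 higher and 0 to 502 lower in heart (the highest without A29), and 5 to 2863 for the difference (2863 without A29). For Elavl1 in heart the log2 fold change ranged from -0.14 to 0.14, and it turned to -0.25 with median-of-ratios scaling, -0.23 with quantile normalization, -0.12 without mitochondrially encoded genes and -0.19 with array weights. For Elavl1 in scWAT it turned to -0.19 with the covariates, and kept its direction under the other alternatives run.

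Lists whose test turned, with their median log2 fold change there, were these. Lipolysis in scWAT stood at 0.12 in the shared fit, 0.12 by fry, 0.16 with array weights, 0.22 in the plain style, 0.10 with at least 5 TPM, 0.093 with median-of-ratios scaling, 0.13 with quantile normalization, 0.089 with the covariates and between -0.060 and 0.23 on leaving out a library. In scWAT, targets of HuR stood at -0.040 with array weights, -0.31 with the covariates and between 0.048 and 0.29 on leaving out a library, and inflammatory cytokines at 0.089 with the covariates and between 0.056 and 0.63. Oxidative phosphorylation stood at -0.045 with median-of-ratios scaling and between -0.059 and 0.060, fibrosis between -0.49 and 0.076, fatty acid oxidation between -0.0060 and 0.14, and B cell between -0.22 and 2.48, lowest without A26. The skeletal muscle list stood at -0.32 with the covariates, which contain its own mean. In heart, by fry, glycolysis stood at 0.14 and the receptors at 0.038, and mitochondrially encoded transcripts at -0.047 with quantile normalization.

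Genes of scWAT that turned with the covariates were Ndufb8 at 0.20, Trem2 at 0.88, Elovl5 at -0.27, Sirt1 at -0.014, Cr2 at -0.41, Cd3d at -0.23, Myh4 at -0.32, Actn3 at -0.20, Tnnt3 at -1.77 and Mylpf at -1.43.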

Other observations

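The tests of family variants and of mitochondrial RNA for the genes apart in both tissues were chosen only after the result had been seen, the second set of gene positions after the outcome of the first.

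Further lists in heart did not pass. Secreted adipose factors, such as the adipokines, had a median log2 fold change of 0.72 after subtracting the median of all genes, with 13 of 24 members higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.164), and passed without A29 (adjusted p = 0.021 by camera and 0.0023 by fry). This list did not pass there with an estimated correlation (camera adjusted p = 0.651). The interferon response stood at 0.37 over 24 members (camera adjusted p = 0.073) and passed in 9 of 20 alternatives (lowest adjusted p = 0.0012, without A29), skeletal muscle at 0.24 over 5 (0.333) and commonly cited targets of HuR at 0.05 over 27 (0.698). Without A29 neither of these 2 passed by camera (adjusted p = 0.57 and 0.297), though both did by fry (0.011 and 0.044), and the targets of HuR stood at 0.20, with 13 of 28 members higher and 2 lower past the threshold over all genes. Lower values, with the adjusted p of camera in parentheses, were those of glycolysis at -0.11 (0.130), adrenergic, angiotensin and natriuretic receptors at -0.22 (0.154), smooth muscle and pericyte at -0.11 (0.187), endothelial at -0.10 (0.297), AU-rich element binding proteins at -0.18 (0.333) and cholesterol synthesis at -0.04 (0.757). Erythroid genes stood at 0.03 and immediate early genes at 0.01 (0.946 for both), though their tests pointed down. Before that subtraction the medians of glycolysis (0.14) and of the receptors (0.04) were above 0 while their tests pointed down.

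In scWAT, lists that did not pass with a positive median log2 fold change were immediate early genes at 0.45 (0.056), mitochondrially encoded transcripts at 0.29 (0.056), AU-rich element binding proteins at 0.23 (0.057), inflammatory cytokines at 0.40 (0.075), macrophage at 0.33 (0.121), unfolded protein response at 0.19 (0.193), interferon response at 0.19 (0.226), heat shock at 0.32 (0.247), fatty acid oxidation at 0.07 (0.338), Schwann cell and nerve at 0.47 (0.338), fibroblast and adipose progenitor at 0.21 (0.40), adrenergic receptors at 0.23 (0.405), cardiac hypertrophy and fetal program at 0.52 (0.454), neutrophil at 0.41 (0.454), endothelial at 0.09 (0.480), calcium handling at 0.07 (0.921) and lipolysis at 0.12 (0.963), with the camera adjusted p in parentheses. Those with a negative median were cholesterol synthesis at -0.51 (0.056), complement and acute phase at -0.14 (0.097), erythroid at -0.98 (0.109), cell cycle at -0.23 (0.111), fibrosis at -0.30 (0.146), secreted adipose factors at -0.03 (0.226), glycolysis at -0.14 (0.237), smooth muscle and pericyte at -0.10 (0.290), circadian clock at -0.12 (0.295) and oxidative phosphorylation at -0.01 (0.839). The median and the test pointed opposite ways for calcium handling, lipolysis and oxidative phosphorylation, and for glycolysis the difference of list means was 0.002.

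Other splits of the libraries were used to ask whether the counts exceed chance. In scWAT, 3 of 56 splits gave at least the real 3 genes, and the highest other gave 24, which follows the name styles (A5, A14 and A24 against the rest), a structure of the samples other than genotype; with the style as a covariate 2 genes were higher and none lower. At least 6 gene lists passed in 54 of the 56 splits, up to 22. In heart, 4 of 35 splits gave at least the real 6 genes, and the highest other gave 3850, with A5, A7, A14 and A29 on the same side, a structure set by A29. Another gave 1246, with A5, A25, A29 and A31 on the same side. It put wild-type and knockout-labelled hearts on both sides, so it follows neither the label nor A29 alone. At least 20 lists passed in 12 of the 35, up to 23. Chance is not excluded for these 4 counts.

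The overlap of 1 gene, Gm5905, was reached by 1 of 100 splits of the mice, the real one, and the highest other gave 0. A split could give an overlap only if it called genes in both tissues, and most splits of a tissue's libraries called none. An overlap of 0 was therefore likely from the start, and this test does not exclude chance. Gene levels apart between all mice of the groups in both tissues, by a gap above 0.3 log2 in each, a gap chosen after seeing the data, were found for mt-Nd3, Gm5905, Pttg1 and Fbxo44, all higher in libraries labelled knockout. These 4 genes were reached by 1 of 135 splits of the mice, the real one, and the highest other gave 3. Pttg1, which encodes securin, stood at 4.40 to 35.7 TPM in wild-type hearts and 53.0 to 64.4 TPM in hearts labelled knockout, and at 6.11 to 41.9 TPM and 69.3 to 78.6 TPM in scWAT, and A29 was among the high hearts. The wild-type mice also differed among themselves, alike in both tissues. A7 and A14 had 4.40 and 4.79 TPM of Pttg1 in heart and 6.11 and 8.01 TPM in scWAT. A5 and A8 had 35.7 and 28.6 TPM in heart and 38.7 and 41.9 TPM in scWAT. Fbxo44 was highest among wild-type libraries in A14 in both tissues, at 5.70 TPM in heart and 3.82 TPM in scWAT.

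Inherited variants that differ between the family of the mice labelled wild-type and that of the mice labelled knockout are a candidate explanation for genes of this kind. If so, such genes may neighbour each other in the genome more often than random genes, though such variants do not require it. The test took genes apart in heart, whether or not they were apart in scWAT. Of 11 heart genes apart by at least 0.5 log2, 2 neighbouring pairs were found, Gm13212 with Znf41-ps and Znf41-ps with Zfp982, all on chromosome 4. The pairs hold none of mt-Nd3, Gm5905, Pttg1 and Fbxo44 and say nothing on the source of those genes. Gm13212, Znf41-ps and Zfp982 are taken up next. Of these, Zfp982 did not pass the test of genes, and Gm13212 and Znf41-ps lost their calls on leaving out any of 6 single hearts. With RefSeq positions only 8 of the 11 genes could be placed, which voids that test (2 pairs, permutation p = 0.0006 against 10000 random lists). With GENCODE positions all 11 were placed and the 2 pairs again exceeded random lists (permutation p = 0.0009), which is in line with inherited variants for the chromosome 4 genes, while these pairs rest on 3 genes of a zinc finger cluster whose similar members may share reads. A larger mitochondrial share is argued against as the source of mt-Nd3, since the other mitochondrially encoded genes had a median heart log2 fold change, not adjusted for the shift of all genes, of -0.33, and at most 0.31, against 2.61 for mt-Nd3. A variant of the mitochondrial genome was not tested.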
